A study of Rattus norvegicus with 10 samples.

How the data were processed

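Gene expression was measured in the livers of 10 rats of the Wistar/ST stock fed a high-fat diet, with 1 Affymetrix array of the rat genome per animal. Per the labels' protocols, 5 rats received dried mulberry leaf powder suspended in carboxymethylcellulose by gastric probe at 500 mg per kg body weight per day and 5 control rats received 0 mg per kg per day, and livers were taken after 7 weeks. Liver pieces were kept in RNAlater, total RNA was extracted with RNAiso, and biotinylated cRNA was made from 2 µg of total RNA, per the labels' protocols. Groups and rat numbers were taken from the sample titles. The labels describe each sample as the liver of a separate rat, so the spread between arrays includes the spread between animals.

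The authors deposited 1 table of linear signal intensity values, with 1 intensity per probe set and array for 31099 probe sets. The submitters' processing notes name MAS5 and the affy package without a version or a role. In the table, the mean intensity after trimming 2% of the values was 500 on every array and the lowest intensity was 1, so the intensities were used as already scaled between arrays. Detection calls were not used here. Median intensity was between 97.5 and 118 per array, and between 82 and 139 values per array stood at the lowest value of 1. The number of arrays limits the precision, and intensities of different probe sets were not read as relative RNA amounts of different genes. They were compared for the filter, for the choice of a gene's probe set and for the Gapdh and beta-actin ratios given below.

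From these values log2(intensity + 16) was computed, so differences of dim probe sets are understated. The 57 control probe sets were left out, and so were probe sets at or under the 40th percentile of the mean log2 value over the 10 arrays, which lay at 6.27 on the log2 scale, or an intensity of 61.1. This left 18625 of 31042 probe sets. Mulberry and control rats were compared in a two-sided linear model per probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Differences are given as mulberry minus control on the log2(intensity + 16) scale, with the standard error (SE) of the model, and group means as mean ± SD of linear intensity. Single values per rat were compared by a two-sided exact permutation test over all 252 assignments of 5 and 5 rats, whose smallest p is 0.00794. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.

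Gene names came from the platform annotation and were matched to RefSeq genes of the rat assembly GRCr8 by Entrez identifier, for names only; no coordinates are given. Of the probe sets other than controls, 20826 carried 1 symbol, 436 several and 9780 none that was used here. Of those with 1 symbol, 20764 were matched by identifier and 0 symbols were updated. A gene was represented by its tested probe set with the highest mean log2 value, which gave 10328 genes. Some genes that the naming rule also asked for are not reported here.

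Fixed before the data were examined were the test, the filter, 35 gene lists written from textbook knowledge, the naming rule and the alternative settings given next. The lists covered mitochondrial and peroxisomal fatty acid oxidation, microsomal omega-oxidation and PPAR-alpha targets, ketone body synthesis, fatty acid synthesis, triglycerides and lipoproteins, cholesterol, bile acids, glycolysis, gluconeogenesis, oxidative stress defence, xenobiotic metabolism, growth hormone and sex-biased genes, acute-phase, interferon, unfolded protein and heat shock responses, the circadian clock, immediate early genes, the cell cycle, the respiratory chain, ribosomal proteins, the proteasome and amino acid catabolism. They also covered extracellular matrix and markers of hepatocytes, macrophages, lymphocytes, neutrophils, endothelium, stellate cells, bile ducts, red blood cells, pancreatic acini and adipocytes. Of 623 list entries, 553 matched a named probe set. Lists with at least 4 tested members (31 lists) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. The rule named the 10 genes with the largest rise and fall among those past the threshold, filled where fewer passed to 5 per direction with the smallest unadjusted p, then 2 members per list with the smallest unadjusted p, and a fixed set of lipid and oxidative stress genes.

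Alternative settings, also fixed then, were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, a median shift, no variance trend, array weights, the replicate number as a block, 1 probe set per gene, a rank product with 100 permutations, an adjusted p under 0.1 and leaving out each array in turn. For the lists they were an estimated correlation, the exact permutation test of list means per rat, fry, the median over a gene's probe sets, no filter, a pseudocount of 1, quantile normalization, the block and leaving out each array. With arrays left out, each gene in a list kept the probe set chosen over all 10 arrays. Chosen after seeing the data were a model with the first principal component as a covariate, models without control rats 1 and 3 or without control rat 5 and mulberry rat 5, and, for lists, an estimated correlation with arrays left out. The model was tested on simulated data for the mulberry against control comparison of 18625 probe sets. Changes were added to the residuals of these arrays about their group means. There limma recovered 6 of 67 probe sets changed by 0.5 on the log2 scale, 42 of 67 changed by 1 and 60 of 66 changed by 2. Such residuals leave unchanged probe sets with a group difference of 0, so the 0 false calls were fixed by construction. The added differences likewise carried no sampling error. On simulated independent noise with each probe set's own spread, limma recovered 9 of 67, 48 of 67 and 59 of 66 for the same sizes. Limma made 4 false calls on that noise and the rank product 119. In both simulations the changes of all sizes were added at once, which eases the Benjamini-Hochberg threshold for each.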

Results

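Liver RNA of 10 rats on a high-fat diet was profiled, 5 rats given mulberry leaf powder at 500 mg per kg per day for 7 weeks and 5 control rats given 0 mg per kg per day. Mulberry leaf is a food supplement, and the design asks how it alters hepatic gene expression under a fat-rich diet, in particular fatty acid oxidation, lipid synthesis and the response to oxidative stress. Correlations between arrays over all probe sets lay between 0.957 and 0.975, with a mean of 0.966 within a group and 0.967 across groups. No array measure differed between the groups by more than the spread between rats. The log2 ratio of the 3′ to the 5′ probe set of Gapdh, a measure of RNA integrity, was 0.22 ± 0.16 (SD, n = 5) in control and 0.21 ± 0.13 (SD, n = 5) in mulberry rats (exact permutation p = 0.913). For beta-actin the same ratio was higher, at 1.77 ± 0.22 in control and 1.64 ± 0.27 in mulberry rats (SD, n = 5 each, exact permutation p = 0.405). Like ratios in both groups do not show that the RNA was intact.

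The livers of mulberry and control rats differed little beyond the spread between animals. The lipid gene with the largest log2 difference was Scd, the desaturase that makes monounsaturated fatty acids, with an intensity of 6530 ± 4211 in control and 2117 ± 1183 in mulberry rats (SD, n = 5 each). Among genes with a symbol and the smallest unadjusted p, Ccdc186 was measured at 118 ± 14.5 in control and 178 ± 13.7 in mulberry rats. Lgals3bp, a secreted galectin-binding glycoprotein, was at 444.9 ± 61.2 in control and 632 ± 67.6 in mulberry rats. S100a9, a calcium-binding protein abundant in neutrophils, stood at 232 ± 31.0 in control and 132 ± 41.3 in mulberry rats. Missing the limma test with these were, on the higher side, Cux2 (+0.87 ± 0.24), a transcription factor of female-type rodent liver, Zfp523 (+0.52 ± 0.15) and the secreted phospholipase Pla2g12a (+0.47 ± 0.14), where differences are log2 with the SE of the model. On the lower side they were Bcl3 (-0.38 ± 0.11), a relative of the NF-kB inhibitors, Borcs6 (-1.28 ± 0.39), whose mulberry mean intensity of 40.6 lay under the filter level of 61.1 and which was also low in control rat 3, the kinase Mok (-0.52 ± 0.17) and Eif4ebp3 (-0.51 ± 0.17), a repressor of translation initiation. Ccdc186 (+0.54 ± 0.13), Zfp523 and Bcl3 were the 3 named genes whose groups did not overlap. Over all genes, 33 of 10328 (0.32%) had groups that did not overlap, against 0.794% by chance.

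With limma, 0 of 18625 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.9999. Among those that missed was a probe set without a symbol (+1.14 ± 0.20), so the naming rule did not name it. Its unadjusted limma p was 6.32e-05, against 0.00136 for S100a9, the smallest among the named genes. Its mean intensity was 50.7 in control rats, under the filter level of 61.1, and 130 in mulberry rats. It was picked out after its values were seen. At an unadjusted p under 0.05 there were 325 probe sets, 200 higher and 125 lower with mulberry, where chance alone gives 931. The rank product, run on the same values, called 26 probe sets, 19 higher and 7 lower, but it also made 119 false calls on simulated noise. Of the named genes it called 4, Cyp2c12 and Bhlhe41 higher and Scd and Borcs6 lower. On simulated independent noise, limma recovered changes of 1 on the log2 scale for 48 of 67 probe sets. Changes of 0.5 were recovered for 9 of 67, so shifts of the smaller size would mostly be missed. Changes of 0.5, 1 and 2 were added in the same run, which eases the adjusted threshold. Recovery can be lower where few probe sets change, so these rates do not show that most changes of 1 would be found here.

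**Figure D1:**
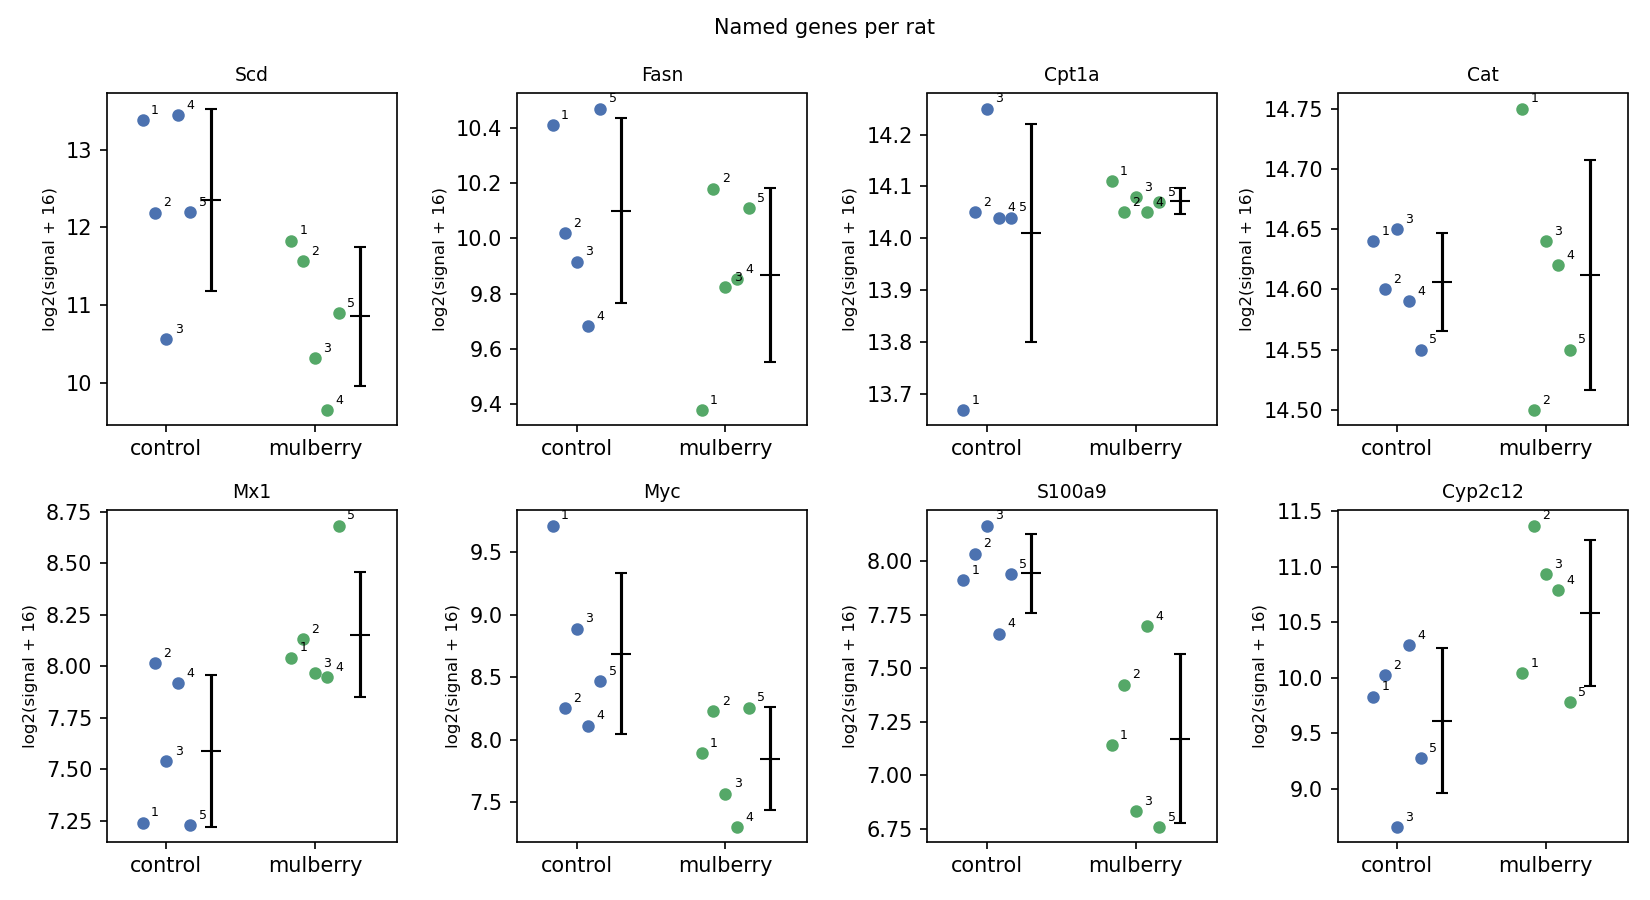
Log2(intensity + 16) of 8 named genes in each rat, with the rat number beside each point and the group mean ± SD (n = 5) as a bar. The vertical scales differ between genes. Scd spreads from 10.56 to 13.45 in control rats.

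Genes of fatty acid oxidation did not pass the list tests, and their medians lay close to 0. Cpt1a, which carries out the rate-limiting entry of long-chain fatty acids into mitochondria, differed by +0.064 ± 0.093 (SE), a sign that turned without control rat 1. Slc22a5, the carnitine transporter, was at +0.22 ± 0.14 and Echs1, the short-chain enoyl-CoA hydratase, at -0.12 ± 0.10. Of the 20 mitochondrial oxidation genes tested, 13 had a higher and 7 a lower mean, with a median of +0.018 (camera adjusted p = 0.763). In the peroxisomal list 8 of 13 members were higher, among them Hsd17b4 (+0.13 ± 0.088), while the carnitine acetyltransferase gene Crat was at -0.20 ± 0.15; the list's median was +0.026 but its mean (-0.0070) and its test pointed down (adjusted p = 0.9). The omega-oxidation and PPAR-alpha target list, of 15 genes, had a median of +0.014 (adjusted p = 0.854). In it Cyp4a1, a fatty acid omega-hydroxylase, was at -0.0027 ± 0.096, the lipoprotein lipase inhibitor Angptl4 at +0.35 ± 0.20, and Ppara itself at -0.59 ± 0.36, with mulberry rat 2 far below the other mulberry rats. Of the ketone body genes 2 were tested, Acat1 (-0.14 ± 0.12) and Bdh1 (-0.066 ± 0.10), too few for a list test.

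Lipogenic genes had lower means with mulberry in most cases but did not pass the list test. Of 17 genes of fatty acid synthesis and desaturation, 13 had a lower mean, with a median difference of -0.081 (camera adjusted p = 0.063, and adjusted p = 0.943 with an estimated correlation). Scd had the largest difference in the list, at -1.50 ± 0.53. Fasn, the fatty acid synthase, was at -0.23 ± 0.18, the acetyl-CoA carboxylase gene Acaca at -0.18 ± 0.14, the NADPH-supplying enzymes Me1 and Pgd at -0.17 ± 0.12 and -0.16 ± 0.11, and the lipogenic transcription factor Srebf1 at -0.31 ± 0.33, a difference whose sign turned without mulberry rat 4. The list passed the threshold without control rat 2 (median -0.18, adjusted p = 0.00849) and without mulberry rat 2 (median -0.16, adjusted p = 0.00409), but not with the correlation estimated there (adjusted p = 0.535 and adjusted p = 0.39 with an estimated correlation). Triglyceride and lipoprotein genes were split, with 9 of 19 higher and a median of -0.010 (adjusted p = 0.854). Lpin1, a phosphatidate phosphatase, was at -0.58 ± 0.35, and Apob, the structural protein of very-low-density lipoprotein, at +0.16 ± 0.075, with the opposite sign on 1 of its 2 probe sets.

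Sterol and glucose genes did not pass as groups. Cholesterol synthesis and uptake genes had a median of -0.0045 over 20 genes (adjusted p = 0.854), with Stard4, a sterol carrier, at -0.27 ± 0.18 and Nsdhl at +0.084 ± 0.088. Bile acid genes had lower means in 15 of 18 cases (median -0.044, adjusted p = 0.351; without mulberry rat 1, median -0.081 and adjusted p = 0.0221, or adjusted p = 0.382 with an estimated correlation), among them Nr0b2 (-0.36 ± 0.20), a repressor of bile acid synthesis, Slc27a5 (-0.096 ± 0.079) and Cyp7a1 (-0.24 ± 0.26), the rate-limiting enzyme of bile acid synthesis. Of 11 glycolytic genes 8 had a lower mean (median -0.037, adjusted p = 0.73), with Tpi1 at -0.10 ± 0.10 and Pgk1 at -0.087 ± 0.087. The gluconeogenesis and fasting list of 12 genes had a median of -0.041 (adjusted p = 0.131). In it the insulin receptor gene Insr was at -0.21 ± 0.12, pyruvate carboxylase (Pc) at -0.19 ± 0.11 and Pck1, the gluconeogenic carboxykinase, at -0.0090 ± 0.067. That list passed the threshold without control rat 1 (median -0.14, adjusted p = 0.0407), mulberry rat 1 (-0.046, adjusted p = 0.0169) or mulberry rat 4 (-0.087, adjusted p = 0.0461). These calls were lost too (adjusted p = 0.783, 0.382 and 0.98 with an estimated correlation).

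Antioxidant genes did not pass as a group. Of 26 genes of oxidative stress defence, 17 had a higher mean, with a median of +0.023 (adjusted p = 0.894). Catalase (Cat) differed by +0.0040 ± 0.065, a sign that turned with quantile normalization, a median shift or 1 of 3 rats left out. Glutathione peroxidase Gpx1 differed by +0.034 ± 0.10, heme oxygenase Hmox1 by +0.062 ± 0.14 and the quinone reductase Nqo1 by +0.23 ± 0.41, with mulberry rat 3 far below the other mulberry rats, or -0.052 without control rat 5. The glutathione transferase gene Gsta3 was at +0.67 ± 0.45 and Aldh1a1 at -0.20 ± 0.16. Xenobiotic-metabolising genes had a median of -0.056 over 13 genes (adjusted p = 0.351; without mulberry rat 4, median -0.071 and adjusted p = 0.0404, or adjusted p = 0.98 with an estimated correlation), led by the carboxylesterase gene Ces2c (-0.36 ± 0.16) and Cyp3a18 (-0.22 ± 0.16). The growth hormone and sex-biased list of 17 genes, which mixes male- and female-predominant genes, had a median of +0.024 (adjusted p = 0.9), with the female-predominant Cyp2c12 at +0.97 ± 0.34 and the male-predominant urinary protein gene Mup5 at -0.77 ± 0.34, or -0.41 without mulberry rat 1.

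Interferon-responsive genes were higher with mulberry as a group. Of 16 genes, 15 had a higher mean, and the median difference was +0.22 (camera adjusted p = 7.17e-05). This call was lost with the correlation between members estimated from the arrays (adjusted p = 0.943 with an estimated correlation), and the exact permutation test of the list mean per rat gave p = 0.0635. Mx1, an antiviral GTPase, was at +0.56 ± 0.20 and Irf7, a transcription factor of the interferon response, at +0.43 ± 0.18, and mulberry rat 5 stood apart as the highest for both. The list mean per rat, relative to all rats, ranged from -0.47 in control rat 5 to 0.37 in mulberry rat 5; without control rat 5 the median was 0.11 (adjusted p = 0.0178, or adjusted p = 0.968 with an estimated correlation). Without both of these extreme rats it was 0.086 (adjusted p = 0.376). The lymphocyte list (12 genes, median +0.023, adjusted p = 0.646) did not pass, with Cd4 at +0.29 ± 0.18 and Cd74 at +0.26 ± 0.19. Macrophage and Kupffer cell markers were higher in 10 of 13 cases (median +0.12, mean +0.015, adjusted p = 0.763), with the lysosomal marker Cd68 at +0.39 ± 0.18 but the lipopolysaccharide receptor Cd14 at -0.38 ± 0.15. That list passed without control rat 3 (median 0.24, adjusted p = 0.0303) or mulberry rat 3 (0.26, adjusted p = 0.0013), but not with the correlation estimated there (adjusted p = 0.802 and adjusted p = 0.925 with an estimated correlation). Both neutrophil genes tested, too few for a list test, had lower means, S100a9 at -0.77 ± 0.19 and its partner S100a8 at -0.62 ± 0.27, or -0.36 without mulberry rat 3. Acute-phase genes had a median of +0.046 over 17 genes (adjusted p = 0.641), with the chemokine Cxcl10 at +0.35 ± 0.19, or +0.17 without control rat 5, and the NF-kB inhibitor Nfkbia at -0.22 ± 0.16.

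Immediate early genes, which respond within minutes to growth factors and stress, were lower with mulberry as a group. Of 12 genes, 9 had a lower mean, and the median was -0.25 (camera adjusted p = 0.0104). The call was lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). The exact permutation test of the list mean gave an unadjusted p = 0.31, or 0.952 adjusted over the 31 lists. Myc was at -0.84 ± 0.29 and the stress-inducible Gadd45b at -0.65 ± 0.29. Control rats 1 and 3 had list means of 0.65 and 0.60 while the other control rats lay between -0.32 and -0.11, and mulberry rats lay between -0.35 and 0.063. The call ended without control rat 1 (median -0.14, adjusted p = 0.396), control rat 3 (-0.053, adjusted p = 0.178), mulberry rat 2 (-0.24, adjusted p = 0.109) or mulberry rat 5 (-0.19, adjusted p = 0.0798), and the direction turned without control rats 1 and 3 together (0.11, adjusted p = 0.622).

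**Figure D2:**
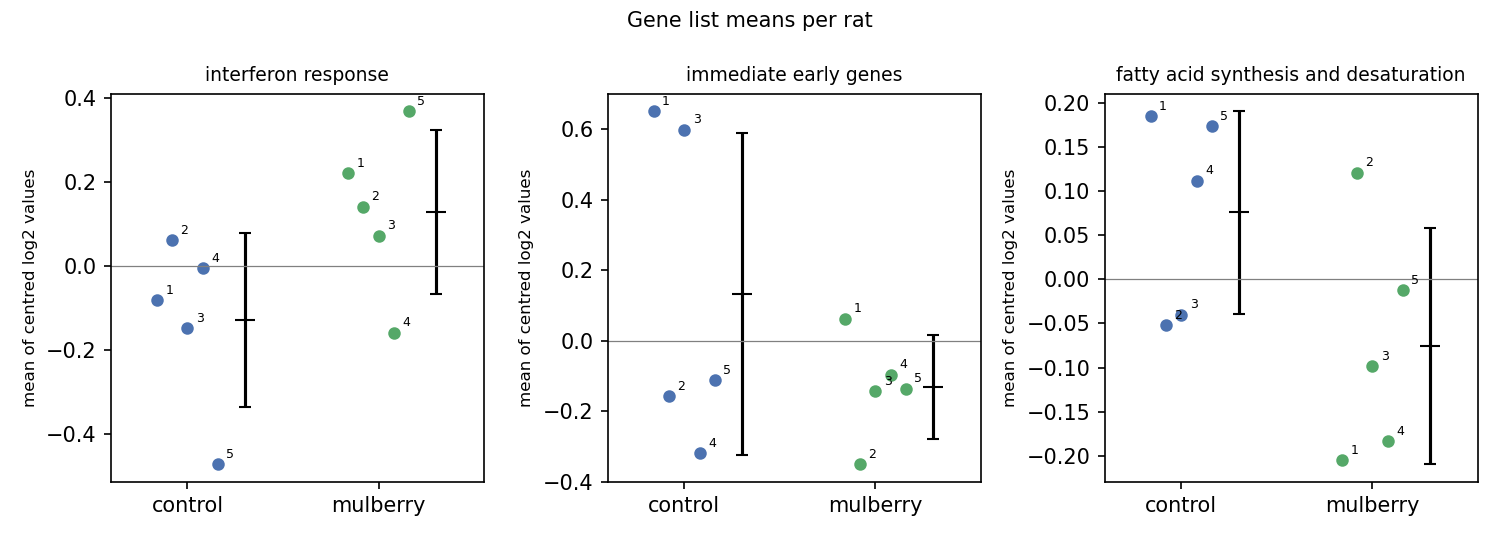
Mean log2 value of the members of 3 gene lists in each rat, each gene centred on its mean over the 10 rats, with rat numbers beside the points and the group mean ± SD (n = 5) as a bar. Control rats 1 and 3 stand at 0.65 and 0.60 for the immediate early genes, and control rat 5 at -0.47 for the interferon list.

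Stress, clock and growth genes did not pass as groups. The unfolded protein list (19 genes, median -0.013, adjusted p = 0.763) held the chaperone gene Calr at +0.16 ± 0.11 and Ddit4 at -0.30 ± 0.21. Heat shock genes were higher in 7 of 9 cases (median +0.045, adjusted p = 0.727), with Dnaja1 at +0.12 ± 0.078 and Hspd1 at +0.11 ± 0.091. The circadian clock list of 16 genes had a median of -0.0033 but a mean of +0.13 and a test pointing up (adjusted p = 0.56), with the clock repressor genes Bhlhe41 at +0.95 ± 0.47 and Nr1d2 at +0.26 ± 0.16. Cell cycle genes had a median of +0.0070 and a mean of -0.027 over 13 genes, with the test pointing down (adjusted p = 0.763); Mcm3 was at -0.48 ± 0.26 and Birc5 at -0.21 ± 0.19.

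Genes of the basic cell machinery had list medians within 0.05 of 0 on the log2 scale. The respiratory chain list had a median of -0.015 over 25 genes (adjusted p = 0.763), with Ndufa2 at -0.13 ± 0.11 and Ndufs1 at +0.12 ± 0.14. Ribosomal protein genes were higher in 14 of 16 cases (median +0.039, adjusted p = 0.56), with Rpl5 at +0.10 ± 0.079 and Rpl3 at +0.10 ± 0.090, and passed without control rat 3 (median 0.11, adjusted p = 0.00246; adjusted p = 0.802 with an estimated correlation). Proteasome genes (19 genes, median +0.028, adjusted p = 0.854), with Psma3 at -0.12 ± 0.11 and Psma4 at +0.075 ± 0.081, also passed without that rat (median 0.12, adjusted p = 0.0255; adjusted p = 0.802 with an estimated correlation). Amino acid and urea cycle genes had a median of +0.0060 and a mean of -0.011 over 23 genes, with the test pointing down (adjusted p = 0.854); Kmo was at +0.12 ± 0.086 and Glud1 at -0.11 ± 0.083.

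Markers of cell types and matrix did not pass as groups. Hepatocyte markers were higher in 10 of 11 cases, though only slightly (median +0.037, adjusted p = 0.727), with Alb at +0.11 ± 0.13 and Ahsg at +0.068 ± 0.080. Extracellular matrix genes were higher in 14 of 17 cases (median +0.056, adjusted p = 0.388), with the collagen cross-linking enzyme gene Lox at +0.38 ± 0.22 and Col1a2 at +0.29 ± 0.17; without control rats 1 and 3 the median was 0.23 (adjusted p = 0.0301, or adjusted p = 0.799 with an estimated correlation). Stellate cell markers (10 genes, median +0.037, adjusted p = 0.763) held Reln at +0.20 ± 0.12 and Col1a1 at -0.32 ± 0.24, the latter with the opposite sign on 1 of 2 probe sets. Endothelial markers (12 genes, median +0.015, adjusted p = 0.885) held Emcn at +0.22 ± 0.13 and Eng at -0.16 ± 0.11. Bile duct markers (4 genes, median -0.048, adjusted p = 0.763) held Krt19 at -0.16 ± 0.26, or +0.0094 without mulberry rat 2, and Slc4a2 at -0.075 ± 0.13, or +0.019 without mulberry rat 4. Red blood cell markers (4 genes, median -0.047, adjusted p = 0.763) held Slc4a1 at -0.30 ± 0.28, or -0.0094 without mulberry rat 1, and Hbb at +0.15 ± 0.14. Pancreatic acinar genes (2 tested), with Cela1 at -0.19 ± 0.16 and Cpb1 at +0.16 ± 0.31, and adipocyte genes (3 tested), with Cfd at +0.24 ± 0.30 and Cidea at +0.083 ± 0.18, were too few for a list test.

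Over the 31 lists, camera called 2, the interferon and immediate early gene lists, and 0 with an estimated correlation, with fry or with the exact permutation test of list means. The number of list members with an adjusted p under 0.05 was 0 over all genes with limma and 0 adjusted over the list alone, in each of the 31 lists, and the counts at an unadjusted p under 0.05 were at most 2 per list. Camera called 4 lists without control rat 3, mulberry rat 1 or mulberry rat 4, and 1 without mulberry rat 5. For 65 of the 91 named genes, leaving out 1 rat moved the difference by over 1.5 times, which takes little where a difference is near 0. It did so for 0 of the 10 named for the smallest unadjusted p. That choice itself favours differences large against the spread between rats, so it does not show that they are more stable. The sign turned without 1 rat for 13 of the 91 named genes, which were Bdh1, Cat, Cidea, Cpb1, Cpt1a, Cyp4a1, Gpx1, Hmox1, Krt19, Nqo1, Pck1, Slc4a2 and Srebf1.

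**Figure D3:**
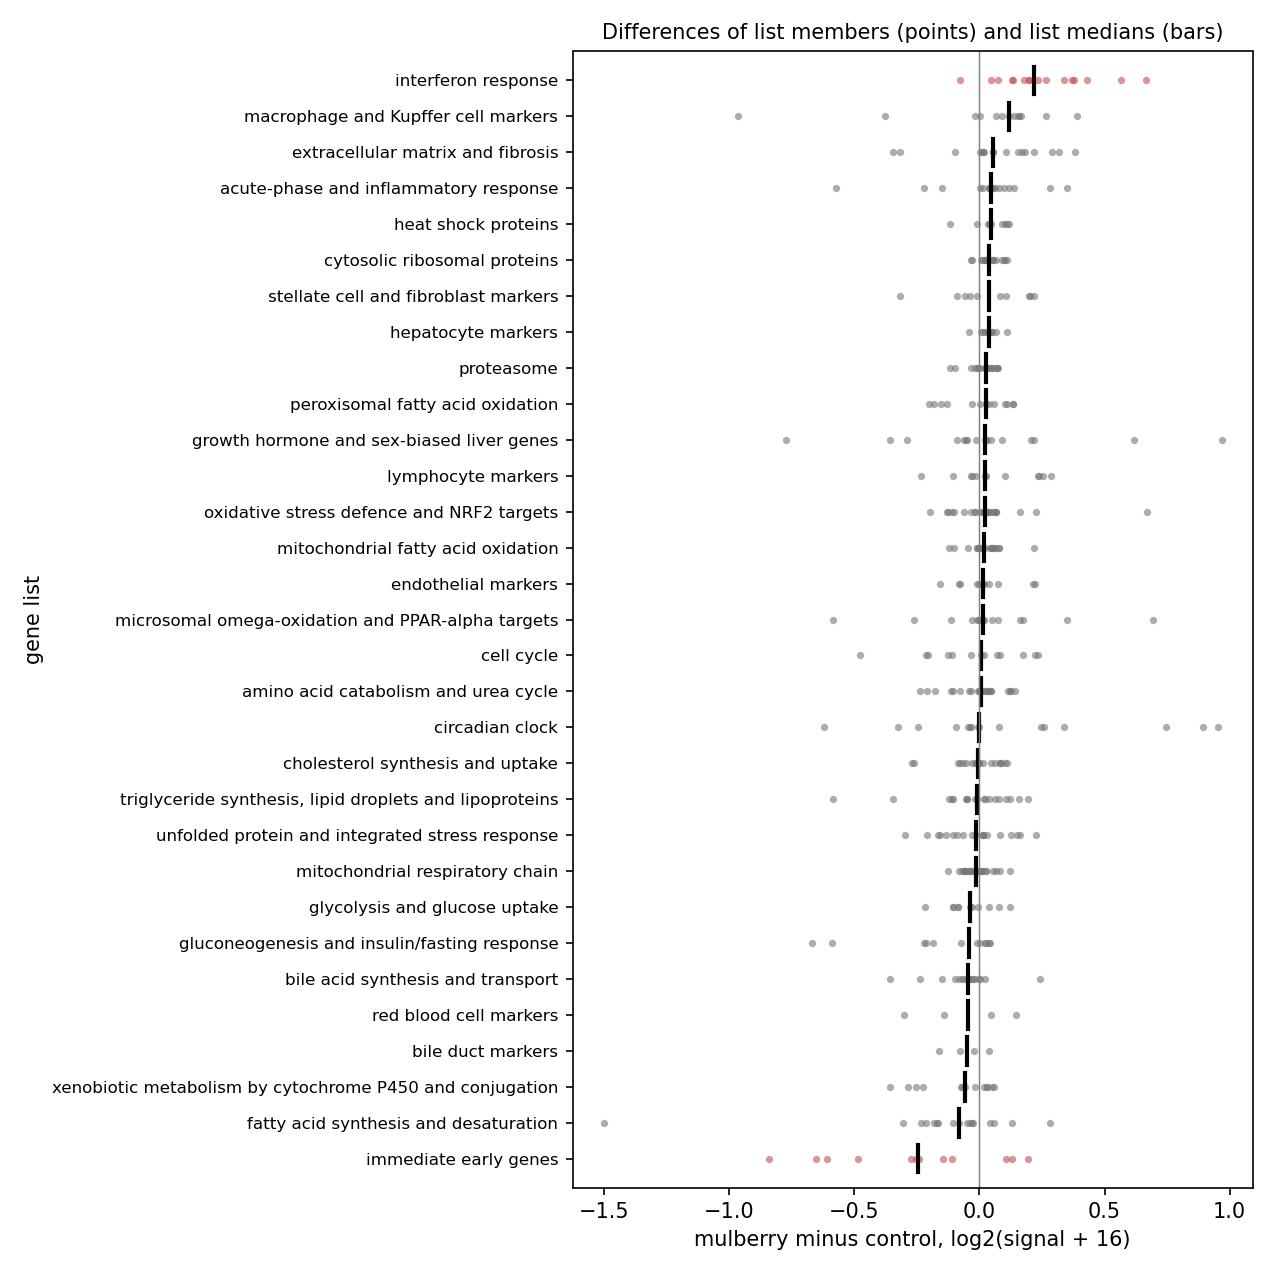
Log2 difference, mulberry minus control, of each tested member (points) of the 31 gene lists, with the list median as a bar and the lists called by camera in red. The interferon list has the highest median at +0.22 and the immediate early gene list the lowest at -0.25.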

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

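For the immediate early gene and interferon lists, camera on all arrays, with the preset or an estimated correlation, was fixed beforehand. So was leaving out each array in turn at the preset correlation. Other tests of these lists given here were chosen only after the lists' results were seen. A rat was singled out where its gap to the nearest other rat of its group took more than 0.71 of the group's range. This picked out 20 sets of 5 values, or 7.94% of those looked at, where chance picks about 1 in 20.

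Among control rats, log2(intensity + 16) was low in rat 3 for Borcs6 (5.46, others from 7.20 to 7.74) and Srebf1 (10.88, others from 11.66), and high in rat 3 for Alb (15.31, others up to 14.81) and Ahsg (15.17, others up to 15.01). It was low in rat 2 for Pgd (9.64) and in rat 5 for Me1 (9.64), and the circadian clock list mean was low in rat 1 (-0.32). Among mulberry rats, values were low in rat 4 for Lgals3bp (9.04, others from 9.38), in rat 5 for Zfp523 (6.97), in rat 3 for Nfkbia (10.30) and Nqo1 (9.28, others from 10.98), and in rat 1 for Nr1d2 (11.31). Mulberry rat 2 was low for Ppara (5.38, others from 7.19), for Col1a1 (5.72, others from 6.79) and for the list means of extracellular matrix (-0.11) and stellate cell genes (-0.27). Mulberry rat 1 was low for red blood cell genes (-0.50) and mulberry rat 4 high for Hspd1 (14.06).

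Mulberry rat 5 was high for Mx1 (8.68, others up to 8.13) and Irf7 (10.12, others up to 9.45), members of the interferon list. Chance was not excluded: of 100 splits of the 10 arrays into 5 and 5, the real one included, 3 gave that list a camera adjusted p as small as the real 7.17e-05, but 34 gave such a p to whichever list was strongest in the split, down to 4.03e-11. With the preset correlation the call held without each array (adjusted p at most 0.0178), but it was lost in all these fits with an estimated correlation (adjusted p from 0.494 to 0.987), and the median was 0.11, not 0.22, without control rat 5. Without control rat 5 and mulberry rat 5 together, whose removal as the extremes of the list lowers the difference by construction, the adjusted p at the preset correlation was 0.376. More lymphocytes or macrophages in the mulberry livers may account for the call: the interferon list exceeded the lymphocyte list by 0.19 (exact permutation p = 0.135) and the macrophage list by 0.24 (exact permutation p = 0.397), gaps too uncertain to exclude this, and an effect of mulberry leaf stays open as well.

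The immediate early gene list was highest in control rats 1 and 3. Chance was not excluded, as 23 of 100 splits gave a camera adjusted p as small as the real 0.0104 (adjusted p = 0.943 with an estimated correlation) and the smallest of the others was 4.51e-07. Without both rats the median difference was 0.11, but removing control rats picked for high values raises it by construction, and the call also ended without mulberry rat 2 or mulberry rat 5, so whether it rests on those control rats alone stays open. The log2 3′ to 5′ ratio of Gapdh was not above all the other 8 rats in either control rat. It was 0.338 in control rat 1, just under their highest (0.344). In control rat 3 it was -0.012, under their lowest (0.024) but by less than their SD of 0.13. The log2 beta-actin ratio was 1.67 in control rat 1 and 1.51 in control rat 3, within the other rats' range of 1.29 to 2.10. Degradation would raise these ratios, and neither ratio set both rats above the others. This gave no sign of RNA degradation particular to them but did not exclude it. Handling of single animals before death may raise these genes, which was not tested, and an effect of mulberry leaf stays open.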

How the results depend on the processing

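Models with the first principal component or without the named pairs of rats, picked for extreme list values, were chosen after seeing the data. The limma count of 0 held for every pseudocount, filter, normalization, weighting and array left out, and at an adjusted p under 0.1, while the rank product gave 26 (19 higher, 7 lower). At an unadjusted p under 0.05 the count of 325 became 878 of 31042 with no filter, 171 of 12417 with the 60th percentile filter and 203 of 10328 with 1 probe set per gene, where the number tested differs, and 524 with the first principal component; it was 286 with the replicate block and from 317 to 405 without 1 array. Rat numbers gave no sign of pairing the rats, which does not exclude a pairing: deviations of same-numbered rats correlated from -0.33 to 0.096. Of 5 pairs, 1 correlated best with its own number. The 2 lists called became 1 with no filter, 3 without control rats 1 and 3, 1 without control rat 5 and mulberry rat 5, 0 with an estimated correlation, the exact permutation test or fry, and from 1 to 4 without 1 array; the block left 2. With an estimated correlation, also chosen after seeing the data for these models, 0 of the 31 list calls made without 1 array or a pair of rats held (smallest adjusted p = 0.382). The interferon median of 0.22 kept its size but not its call with an estimated correlation (adjusted p = 0.943), the exact permutation test (adjusted p = 0.952) and fry (adjusted p = 0.976), and was 0.086 without control rat 5 and mulberry rat 5 and from 0.11 to 0.30 without 1 array. The immediate early gene median of -0.25 lost its call under the same 3 tests and with no filter (-0.19, adjusted p = 0.0507), was 0.11 without control rats 1 and 3, and ranged from -0.33 to -0.053 without 1 array. The cause was not tested. Of the other 29 lists, 8 passed in at least 1 alternative, in 13 of 609 values. Of 91 named genes, 14 turned sign in at least 1 of 23 alternatives with limma, each with a difference within 0.31 on the log2 scale, and 0 of these values passed the threshold, while the rank product called 4 (Cyp2c12 and Bhlhe41 higher, Scd and Borcs6 lower). Signal over background limits dim genes such as Borcs6 and Cux2.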

Other observations

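Tests of the female-type genes were chosen only after their values were seen, and the model with the first principal component only after the count of 325 was seen.

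Rats differed from each other in whole groups of genes, in either group. Cholesterol synthesis genes moved together, with a list mean of -0.48 in mulberry rat 4 and 0.43 in mulberry rat 2 relative to all rats (estimated correlation between members 0.472). Macrophage and Kupffer cell markers ranged from -0.64 in mulberry rat 3 to 0.42 in control rat 3 (estimated correlation 0.577), and ribosomal protein genes from -0.17 in control rat 2 to 0.25 in control rat 3 (0.746). Control rat 3 also had the highest list mean for mitochondrial fatty acid oxidation (0.19), the proteasome (0.29) and omega-oxidation and PPAR-alpha targets (0.39).

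The rank product put Tmem14a (+1.72 ± 1.04), the cadherin gene Cdh17 (+1.23 ± 0.71) and Foxo4 (+1.03 ± 0.45) among its 19 higher probe sets. Also among them was Gbp7 (+1.07 ± 0.39), an interferon-inducible GTPase outside the fixed list. The 7 lower ones included Scd, Tenm2 (-1.09 ± 0.44) and the macrophage lysozyme Lyz2 (-0.96 ± 0.53). These examples were chosen after their values were seen. Of 100 splits of the arrays, 93 gave at least 26 rank product calls, up to 274, so chance was not excluded.

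The number of probe sets with an unadjusted p under 0.05 was 325, where 931 are due by chance. Other splits of the same arrays ranged from 288 to 3254, so a count under 931 was not particular to the real split. Of 100 splits, the real one included, 99 gave at least 325, which points to a structure among the rats that cuts across the groups. For calls at an adjusted p under 0.05 all 100 splits reached the real 0, up to 7, and for lists 84 of 100 reached the real 2, up to 14, so chance was not excluded for either. The first principal component held 26.2% of the variance, with control rat 3 at 44.9 and mulberry rat 3 at -29.0. With it as a covariate the count rose to 524, as a shared axis of variation in both groups would predict, though it stayed under 931. The component is the largest axis of these same arrays. Taking it out lowers the spread within groups whatever its source, so the rise cannot decide whether that axis is the cause. What the axis is was not tested. The rats at its ends also had the extreme log2 Gapdh 3′ to 5′ ratios, -0.012 in control rat 3 and 0.344 in mulberry rat 3. Rats between them did not all follow that order. Mulberry rat 2, at 12.3 on the component, had a ratio of 0.269, and mulberry rat 4, at 6.15, had 0.024.

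Some genes known as female-predominant in rat liver had higher means with mulberry: Cux2 (+0.87 ± 0.24), Cyp2c12 (829 ± 338 in control and 1644 ± 718 in mulberry rats, SD, n = 5), A1bg (+0.84 ± 0.49) and the prolactin receptor gene Prlr (+0.27 ± 0.31 on its brightest of 3 probe sets, all higher). Others known as female-predominant were at like levels: Cyp2c7 (+0.050 ± 0.099), Cyp2a1 (+0.024 ± 0.089) and Cyp3a9 (-0.015 ± 0.080). With limma none of the 7 passed, the rank product called Cyp2c12 and A1bg, and the last 5 were chosen after their values were seen. A shift of the liver toward the female pattern is a candidate explanation and would lower male-predominant genes. Over 12 male-predominant genes the mean difference was -0.11 ± 0.060 (SE; exact permutation p = 0.111), with 8 of 12 lower, and without Mup5 it was -0.053 ± 0.063 (exact permutation p = 0.421). Cyp2c11 (-0.015 ± 0.10), Cyp2c13 (+0.030 ± 0.078) and Obp3 (-0.055 ± 0.092) were at like levels. The test left it open, since a small decrease is within the spread. The male-predominant genes had control intensities from 5161 to 33440, where a bright probe set may show little of a decrease, which was not tested. Lower means were still seen in that range, for Mup5 (14690 in control and 9496 in mulberry rats) and Scd (6530 and 2117).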
